A study of Mus musculus with 88 samples.

How the data were processed

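Total RNA was sequenced from nucleus accumbens tissue of female and male mice on a C57BL/6 background, dissected 6 days after surgery. Per the labels' protocols, herpes simplex vectors had delivered a nuclease-dead Cas9 fused to CREB(S133D), a constitutively active form, together with a guide RNA to Fosb or a non-targeted control guide. Vectors that need Cre were given to D1-Cre or D2-Cre mice, and vectors that do not need Cre to further mice, which makes 6 arms by sex and cell type (D1, D2 and both) and 12 groups with the guide. Libraries were ribosomal RNA-depleted, stranded and made with a TruSeq total RNA kit. The submitters' processing notes name Trim Galore, HISAT2, SAMtools, featureCounts from Subread and DESeq2 1.27, with the mm10 build. The gene annotation and the strand setting used for counting are not given in the sources used here.

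The deposited table holds counts of reads per gene, as whole numbers with no normalization, for 55487 genes. Of the 88 labelled libraries 87 were used. A female D2 library with the Fosb guide matched no column, and 1 column matched no label and was left out. Libraries were assigned to groups by the numbers in their titles. Gene identifiers were named from a mouse annotation table, which left 93 without a symbol, and positions and exon lengths came from GENCODE M21 on mm10. A count in no library was found for 6164 genes.

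Total counts ran from 12430387 to 69568367 per library, with a median of 31393804. By group they ran from 15844472 to 41546449 (female D1 control), 25695503 to 59328186 (female D1 targeted), 17523936 to 31174664 (male D1 control), 15030373 to 37346886 (male D1 targeted), 24986394 to 39043867 (female D2 control) and 12430387 to 40936856 (female D2 targeted). In the remaining groups they ran from 24431972 to 69568367 (male D2 control), 25401426 to 60526106 (male D2 targeted), 23326739 to 37533949 (female D1D2 control), 13481753 to 57336235 (female D1D2 targeted), 19360881 to 54013949 (male D1D2 control) and 12615397 to 50154089 (male D1D2 targeted). In 4 libraries the 10 most abundant genes held over 90% of the counts, which lowers the depth left for the others. All of these carried the Fosb guide: female D2 17907 and 18432, female D1D2 19610 and male D1D2 18919.

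Counts were fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with robust dispersion, TMM scaling, the filterByExpr filter by group and a model of 12 groups and sequencing batch. The filter left 25420 genes. Batch 2 held male D2 libraries alone. There were 17 comparisons: Fosb guide against control in each arm, their means over sexes and over all arms, the differences of these effects between sexes and between D1 and D2 arms, and female against male controls. P values were adjusted by Benjamini and Hochberg over all genes of a comparison, at a threshold of 0.05. Log2 fold changes have standard errors from the same test. Group values are CPM scaled by TMM.

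A set of 33 gene lists was fixed before the data were examined, as were the comparisons, the model and the rule for named genes. Lists were tested on log2 CPM (prior count 2) with limma 3.58.1 by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, whose p tests whether a list's genes move one way without comparing them with other genes. Adjustment was over the lists of a comparison. Of 561 tests camera called 196, of which 6 were called with an estimated correlation, while fry called 18. List medians, means and tests can differ in sign, as for the neuropeptide list in female D2 mice (median −0.02, mean 0.07). Fosb levels and mean list levels were compared between guides by exact permutation tests, two-sided, and for male D2 mice also within batches (1260 splits). Correlations across libraries used 100000 resamples in batch 1 and exact enumeration in batch 2. Correlations of fold changes used 100 shuffles of the guides within arms. Means over arms used 10000 resamples within arm and batch.

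Genes were named by the fixed rule. It named Fosb, its neighbours, up to 4 members of each list that passed, and the 8 genes that rose and the 8 that fell most among those that passed with a mean of at least 1 CPM and an established symbol. Where fewer than 5 passed in a direction all of these were named, with up to 3 further genes of the smallest p, said not to have passed. Other genes given with a value are said to be chosen after their values were seen, and members that open a paragraph as examples of a list stand for that list.

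The alternatives set with them were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no batch term, 3 surrogate variables from sva 3.50.0, each arm fitted alone, and leaving out in turn each library of the groups with 4 libraries. For list tests they were the estimated correlation and fry, and for correlations of fold changes a minimum mean of 1 CPM. Batch 1 libraries alone were set for the male D2 results. Settings added after the data were seen are named with their effects. Every comparison was also refitted on 20 other splits of the libraries. The procedure was tested on simulated data, drawn from the negative binomial fit with the real library sizes, in which 200 genes per arm were changed: of genes changed 1.5-fold between 25% and 56% were recovered by arm, and of genes changed 2-fold between 60% and 85%. The changed genes had a mean of at least 1 CPM and all genes were drawn independently. Recovery among lower genes, or under the variation that real libraries share, was not tested. All 3741 pairs of libraries were compared by a chi-square of their counts, and no pair differed by as little as sampling noise, which gives about 1 per degree of freedom. The closest were male D1 targeted 18722 and male D1D2 targeted 18749, of different groups, at 3.63 per degree of freedom against a median of 211, and both were kept. Within groups the lowest of 296 pairs was at 13.4. Intervals for single counts are not given, since every group had replicates. Tables were made with the data.table package (1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.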

Results

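Transcripts of the nucleus accumbens, a reward region built mainly of D1- and D2-type medium spiny neurons, were counted in 87 libraries from female and male mice. A nuclease-dead Cas9 fused to constitutively active CREB had been directed to Fosb by a guide RNA or left with a non-targeted guide. Fosb encodes FosB and its truncated product ΔFosB, AP-1 transcription factors of striatal neurons. The question was what changes in Fosb itself and in other genes when the activator was expressed in D1 cells, in D2 cells or in both. Each of the 6 arms, defined by sex and cell type, was compared as Fosb guide against non-targeted guide, so positive log2 fold changes mean higher with the Fosb guide. Levels are given as TMM-scaled CPM, mean ± SD.

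Fosb was low in all arms, and its difference between guides was within or close to the spread between mice. The RNA came from whole dissected tissue, so Fosb in the targeted cells alone was not measured. The gene (ENSMUSG00000003545) lies on chromosome 7, from 19302696 to 19310051 on the minus strand of mm10. In females with D1 delivery Fosb was at 9.70 ± 2.38 CPM with the Fosb guide (n = 6) and 7.29 ± 1.51 with the control guide (n = 8), exact permutation p = 0.0516. In males with D1 delivery it was at 6.29 ± 1.32 CPM (n = 7) against 4.51 ± 0.389 (n = 4), exact permutation p = 0.0364. In the D2 arms the means ran the other way, with 6.56 ± 2.81 (n = 8) against 7.71 ± 1.86 CPM (n = 8) in females, exact permutation p = 0.196. Targeted library 17907 there was at 13.34 CPM from only 13 counts of Fosb. Without it, a choice made after the values were seen, the targeted mean was 5.59 ± 0.697 CPM, exact permutation p = 0.00342 (0.0205 adjusted over the 6 arms), while edgeR gave −0.47 with 0.113 adjusted over the arms. Males with D2 delivery had 6.31 ± 1.15 CPM (n = 7) against 9.52 ± 3.52 (n = 8), exact permutation p = 0.123, pooled over batches that are unbalanced between the guides. With delivery to both cell types Fosb was at 6.89 ± 2.53 (n = 12) against 6.71 ± 1.93 CPM (n = 8) in females, exact permutation p = 0.988. In males with delivery to both cell types it was at 10.7 ± 5.04 (n = 4) against 7.25 ± 3.36 CPM (n = 7), exact permutation p = 0.255. All these tests were two-sided, and after adjustment over the 6 arms the lowest exact permutation p with all libraries was 0.155.

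The edgeR log2 fold changes of Fosb were 0.41 in female D1, 0.48 in male D1, −0.37 in female D2, −0.30 in male D2, 0.08 in female D1D2 and 0.60 in male D1D2 mice, with standard errors from 0.20 to 0.28. The lowest edgeR p adjusted over the 6 arms was 0.167. Libraries with the Fosb guide lay above the median of their controls in 5 of 6, 6 of 7, 1 of 8, 0 of 7, 6 of 12 and 2 of 4 cases, in the same order. The male D2 libraries came from both sequencing batches, unbalanced between the guides, so the count of 0 of 7 compares libraries across batches. Control means there were 4.839 CPM in batch 1 (n = 2) and 11.1 in batch 2 (n = 6). The lowest male D2 targeted library, at 5.07 CPM, was above the batch 1 control mean. With 2 controls that mean is also their median, so the count does not hold within batch 1 of the male D2 arm. In batch 1 the log2 difference there was 0.35 between 4 libraries with the Fosb guide and 2 controls, exact permutation p = 0.533. In batch 2 it was −0.60, with 7.25 ± 1.04 CPM (n = 3) against 11.1 ± 1.97 (n = 6), exact permutation p = 0.0119. Permuted within batches, the difference was −0.22 with an exact permutation p of 0.352. Without male D1D2 targeted library 18749 the male D1D2 fold change was 0.89, with an edgeR p of 0.0218 adjusted over the arms. That library was the closest of all to male D1 targeted library 18722 in its counts (r = 0.994 on log2 CPM, the second highest of 3741 pairs), at 5.35 and 5.75 CPM of Fosb. Whether these 2 libraries come from 1 mouse is not given in the sources used here. Without both, Fosb was at 0.49 in male D1 and 0.89 in male D1D2 mice, with edgeR p of 0.180 and 0.0232 adjusted over the arms.

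**Figure D1:**
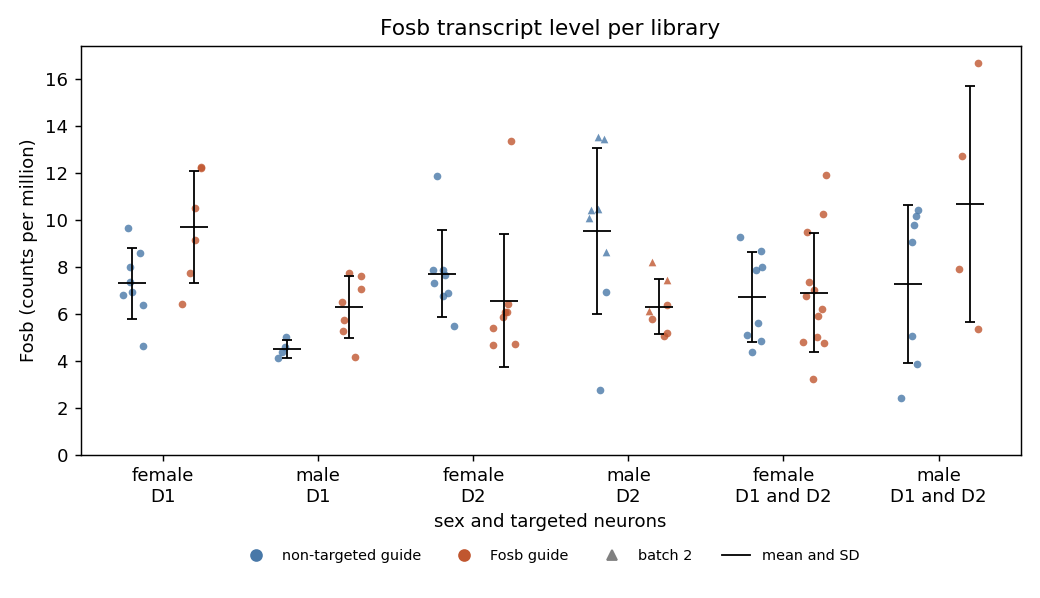
Fosb level in CPM for each library, by sex, cell type and guide, with the mean and SD of each group and batch 2 libraries as triangles. The Fosb guide means lie above the control means in both D1 arms (9.70 against 7.29 and 6.29 against 4.51 CPM) and below them in both D2 arms (6.56 against 7.71 and 6.31 against 9.52 CPM). The male D2 means are pooled over batches that are unbalanced between the guides.

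The 10 genes annotated beside Fosb, which include the DNA repair genes Ercc1 and Ercc2, the actin regulator Vasp and the reticulon Rtn2, did not pass in any arm. The others were Cd3eap, Eml2, Gpr4, Klc3, Opa3 and Ppp1r13l. Fold changes above 0 were counted for 3 of the 10 in female D1, 9 in male D1, 8 in female D2, 8 in male D2, 5 in female D1D2 and 5 in male D1D2 mice. All lay between −0.28 (Rtn2, male D1) and 0.46 (Vasp, male D1). The lowest p belonged to Ercc2 in male D1 mice (log2 fold change 0.38, p = 0.0185), at 0.185 adjusted over the list alone.

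In female D1 mice Gm9887, a gene with a placeholder name, was the single gene that passed, and it fell. Activity-induced genes such as Egr1, Arc and Per1, whose transcripts follow neuronal firing, leaned upward as a group. Genes of cortical glutamatergic neurons such as Fezf2 leaned upward as well, both lists at 0.211 with an estimated correlation. The pro-opiomelanocortin gene Pomc, which encodes peptide hormones, did not pass. Gm9887 fell by 5.48 on the log2 scale (SE 0.85, adjusted p 2.14e-04), from 114 ± 314 CPM (n = 8) to 2.53 ± 0.490 (n = 6). One control library, 16583, held 890.3 CPM of Gm9887 and no gene passed without it. An unadjusted p under 0.05 was found for 1139 genes, and DESeq2, limma-voom and the model with 3 surrogate variables each called 0. Genes of small p that did not pass were Pomc (1.30), Kdm5d (4.72), Ddx3y (4.65), Mgat2 (−1.31), Plrg1 (−0.28) and Vcpkmt (−0.99). Mgat2 was at 118 ± 164 CPM in controls against 47.7 ± 4.15 with the Fosb guide, and Vcpkmt at 13.6 ± 19.5 against 6.82 ± 1.16. Both had control SDs above their means. They lie near Gm9887 (start 69371835) on chromosome 12, from 69184157 and 69577628. The Y-linked Kdm5d and Ddx3y came from targeted library 17376, which held 37.0 CPM of Ddx3y beside 35.2 of Xist. The activity-induced list had a median log2 fold change of 0.23 with 22 of 24 genes above 0 and a camera adjusted p of 3.57e-07, which was 0.211 with an estimated correlation. Its mean log2 CPM was 4.40 ± 0.14 against 4.04 ± 0.22, exact permutation p = 0.00699, or 0.252 adjusted over 36 such tests. The cortical glutamatergic list had a median of 1.90 (camera adjusted p 2.10e-08), or 0.211 with an estimated correlation. In that list 2 genes were higher adjusted over the list alone, against 0 over all genes, among them Fezf2 (2.12), named after its value was seen. The choroid plexus and ependymal list had a median of −0.63 (camera adjusted p 0.0110), or 0.524 with an estimated correlation, with 2 genes lower adjusted over the list alone and 0 over all genes.

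In male D1 mice no gene passed with edgeR. Wdr90, a centriole-associated protein gene, Snapc4, which serves small nuclear RNA transcription, and the chromatin remodelling gene Nfrkb had the smallest p among higher genes. Rps27a, a ribosomal protein gene, and the autophagy gene Atg12 led the lower ones. Ribosomal protein genes lay below 0 as a group, and lymphocyte transcripts above. The count of 0 stood beside 1807 genes with an unadjusted p under 0.05, 0 calls by DESeq2, 0 with 3 surrogate variables and 747 by limma-voom with quality weights. Of these 747 genes, 458 were higher and 289 lower, 550 had an unadjusted edgeR p under 0.05, and all 747 had the same sign in edgeR. Chosen after their values were seen, limma-voom calls were Cpsf1 (0.53), Nfrkb (0.46), Rcan1 (−0.41), Awat2 (−1.13) and Gm16104 (1.47). In edgeR Wdr90 was at 5.66 ± 0.878 CPM (n = 7) against 3.40 ± 0.371 (n = 4), a log2 fold change of 0.73 (SE 0.18, adjusted p 0.686). Other values that did not pass were Snapc4 (0.66), Nfrkb (0.44), Rps27a (−0.74), Atg12 (−0.35) and the spliceosomal RNA gene Rnu2-10 (−4.13). The ribosomal protein list had a median of −0.24 with 0 of 18 genes above 0 (camera adjusted p 2.31e-09), or 0.858 with an estimated correlation. Rps27a was the 1 gene lower adjusted over the list alone, against 0 over all genes. The activity-induced list had a median of 0.26 (18 of 24 above 0, camera adjusted p 0.00321) and the lymphocyte list 0.74 (14 of 15, 2.76e-05). Both were at 0.858 with an estimated correlation. Without control library 17789 the difference in mean log2 CPM of the activity-induced list fell from 0.264 to 0.100 (exact permutation p 0.325). Control library 18383 had a mean log2 CPM of −0.864 in the lymphocyte list, where the other 3 controls had 2.264 to 3.907. Without it the difference in that mean fell from 1.393 to 0.348 (exact permutation p 0.425). Over both sexes of D1 mice, Gm9887 passed (−2.81, SE 0.54, adjusted p 0.0481), though not without library 16583 (−0.09), with 1862 genes at an unadjusted p under 0.05. Limma-voom called 26 genes there (18 higher), among them Egr1 (0.71), Per1 (0.49) and Rcan1 (−0.30), chosen after their values were seen. Fosb was at 0.45 (SE 0.18, p = 0.0168), and Per1 (0.46), Wdr90 (0.48), Zfhx2 (0.58), Ahsa1 (−0.25), Tmem35a (−0.37) and Rnu2-10 (−4.02) did not pass. In the mean of both sexes the activity-induced list had a median of 0.30 (20 of 24 above 0, camera adjusted p 1.59e-07), or 0.356 with an estimated correlation, and 3 genes were higher adjusted over the list alone, against 0 over all genes.

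In female D2 mice no gene passed. The smallest p values belonged to the 5S ribosomal RNA genes n-R5s194, n-R5s193 and n-R5s156 and to Pole2, a subunit gene of DNA polymerase epsilon. The potassium channel gene Kcns2 and the fucosyltransferase gene Fut11 followed. Interferon-stimulated genes and septal markers leaned upward. The unadjusted p was under 0.05 for 421 genes, DESeq2 called 4 (n-R5s193, Gm47301, n-R5s185 and n-R5s33, named after their values were seen), and limma-voom and the 3 surrogate variables called 0 each. Pole2 was at 2.70 ± 1.54 CPM (n = 8) against 37.7 ± 99.2 (n = 8), a log2 fold change of −3.92 (SE 0.80, adjusted p 0.143). Its control SD was above its control mean, and it lies from 69201773 on chromosome 12, between Mgat2 and Gm9887. The 5S genes n-R5s194 (7.99), n-R5s156 (7.02) and n-R5s193 (6.47) had SDs above their means, and Kcns2 (−0.36) and Fut11 (−0.24) did not pass either. Small RNA genes, 5S ones included, held 33.1% and 33.2% of the counts in targeted libraries 17907 and 18432. In the other female D2 libraries they held at most 9.18%. The interferon list had a median of 0.18 (25 of 25 above 0, camera adjusted p 4.28e-05), which was 0.744 with an estimated correlation. The septal and pallidal list had a median of 0.56 (10 of 10, 6.04e-04), or 0.373 with an estimated correlation.

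In male D2 mice 16 genes rose with the Fosb guide, and 14 of them were highest by far in a single library. Setd4, a lysine methyltransferase gene, was the only one of them with a mean of at least 1 CPM and an established symbol. Most of the rest, such as Gm10800, Gm10801 and Gm21738, are predicted genes without a known product. They are not all separate loci. Gm10717, Gm10718, Gm10719, Gm10722 and Gm11168 lie within the span of Gm26870 on chromosome 9, from 3000282 to 3038313. Gm10800 and Gm10801 lie close together on chromosome 2, from 98666547 and 98662237. The splicing factor gene Tra2a, the spliceosome gene Zcrb1 and the DNA polymerase gene Polb were lower without passing. Activity-induced genes leaned downward. Setd4 was at 24.1 ± 39.9 CPM (n = 7) against 8.20 ± 2.75 (n = 8), a log2 fold change of 1.43 (SE 0.29, adjusted p 0.0113). The others were Gm10719 (4.96), Gm10718 (4.50), Gm33838 (4.41), Gm11168 (4.08), Gm10717 (4.01), Gm10801 (3.67), Gm26870 (3.42), Gm21738 (3.37), Gm10722 (3.35), Gm10800 (2.96), Gm41335 (2.75), 4930500H12Rik (2.74), Gm45740 (2.38), Gm47518 (2.33) and Gm13767 (1.47). Targeted library 3632 held 3877 CPM of Gm10800 and 113 CPM of Setd4, and without it 0 genes passed. A further targeted library of batch 2, 3128, was above every control in 15 of the 16 genes, with 410.7 CPM of Gm10800 (controls at most 156.8) and 23.63 of Setd4 (at most 12.53). Targeted library 2756, also of batch 2, was above every control in 1 of the 16. The batch 1 targeted libraries reached at most 10.44 CPM of Gm10800 and 6.144 of Setd4. The 15 genes still tested without 3632 all stayed above 0, with a median log2 fold change of 1.335 (median SE 0.552) against 3.362 (0.635) with it. In batch 1 alone, and with each arm fitted alone, 0 passed as well. Limma-voom called 0, DESeq2 5 (Gm10718, Gm10801, Gm26870, Gm10800 and Gm21738), and 553 genes had an unadjusted edgeR p under 0.05. Tra2a (−0.32), Zcrb1 (−0.34) and Polb (−0.31) did not pass. The activity-induced list had a median of −0.25 with 0 of 24 genes above 0 (camera adjusted p 4.97e-07), or 0.147 with an estimated correlation. The antigen presentation list had a median of 0.57 (13 of 13, 3.80e-13), or 0.153 with an estimated correlation. Its difference in mean log2 CPM was 2.678 in batch 1 (exact permutation p 0.0667), where the 2 controls include the low library 18386. In batch 2 that difference was 0.372 (exact permutation p 0.571). The erythrocyte list had a median of −0.88 (0 of 5, 2.92e-08), or 0.147 with an estimated correlation, with 3 genes lower adjusted over the list alone and 0 over all genes. Over both sexes of D2 mice edgeR called 0 genes, as did DESeq2 and limma-voom, with 609 at an unadjusted p under 0.05. Fosb was at −0.33 there (SE 0.17, p = 0.0528), and Xylb (0.38), Setd4 (0.69), Rnu2-10 (2.74), Arntl (−0.32), Fut11 (−0.18) and Pole2 (−1.78) did not pass.

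In female D1D2 mice no single gene passed, while interferon-stimulated and antigen presentation genes were higher as groups, against controls of which 4 of 8 had very low levels. Pdzph1, which encodes a PDZ and pleckstrin domain protein, the interferon-induced gene Ifi27 and Folh1, a glutamate carboxypeptidase gene, had the smallest p among higher genes. The elastin gene Eln, Klhdc1 and the ciliary gene Togaram1 were lower without passing. Markers of microglia and lymphocytes leaned upward. EdgeR gave 864 genes with an unadjusted p under 0.05. DESeq2 called 2 (Folh1 0.57 and Pdzph1 0.94), limma-voom 194 and the model with 3 surrogate variables 120, all of them higher. Of the 194, 26 had an unadjusted edgeR p under 0.05. The 194 held 17 members of the interferon list, 12 of the antigen presentation list and 6 of the microglia list, and 63 were also among the 120, which held 1, 5 and 5 members of these lists. Chosen after their values were seen, limma-voom calls were Irf9 (1.79), Igtp (2.58), Psmb8 (2.32) and B2m (1.96). With surrogate variables the microglial genes C1qa (0.63), C1qc (0.64), Fcer1g (0.80) and Ctss (0.66) were called, again named after their values were seen. In edgeR Pdzph1 was at 15.7 ± 3.71 CPM (n = 12) against 8.44 ± 4.52 (n = 8), a log2 fold change of 0.91 (SE 0.20, adjusted p 0.332). Ifi27 (0.71), Folh1 (0.53), Eln (−0.86), Klhdc1 (−0.77) and Togaram1 (−0.26) did not pass. Klhdc1, from 69241176 on chromosome 12 near Pole2, was at 14.25 ± 2.92 CPM against 24.9 ± 24.3 in controls. The interferon list had a median of 0.33 (25 of 25 genes above 0, camera adjusted p 1.37e-41), held its call with an estimated correlation (0.0391), and had a fry adjusted p of 0.0513. The antigen presentation list had a median of 0.37 (12 of 13, 8.20e-29), at 0.0335 with an estimated correlation and 0.0401 by fry. No member of either list passed, over all genes or adjusted over the list alone. The mean log2 CPM of the interferon list was 6.50 ± 0.73 against 4.83 ± 2.67, exact permutation p = 0.0512, or 0.278 adjusted over the 36 tests. Of the 8 control libraries, 19754, 19599, 19750 and 19598 had interferon list levels from 1.49 to 3.26 and lymphocyte list levels from −1.85 to −0.29, and the other 4 had interferon levels from 7.13 to 7.63. The microglia list (0.39, camera adjusted p 3.32e-13) and the lymphocyte list (0.63, 2.75e-15) were both at 0.118 with an estimated correlation.

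In male D1D2 mice the single gene that passed, Gm23935, rests on 1 library. The inducible heat shock protein genes Hspa1a and Hspa1b, which buffer misfolded proteins, were higher without passing. Khdc4, a splicing gene, was higher and Adal, Higd2a and Proca1 were lower without passing. Activity-induced genes leaned upward. Gm23935 was at 44640 ± 86010 CPM (n = 4) against 2439 ± 984 (n = 7), a log2 fold change of 4.19 (SE 0.71, adjusted p 0.00192). Targeted library 18919 held 173648 CPM of it, and without that library the fold change was −0.57 and 0 genes passed. Without targeted library 18749 the genes that passed were Dnajb1 (0.62), Gm23935 (4.71), Hspa1a (1.99) and Gm20481 (2.06), named after their values were seen. The unadjusted p was under 0.05 for 818 genes, and DESeq2 called 1, limma-voom 0. Values that did not pass were Hspa1a (1.56), Hspa1b (1.88), Khdc4 (0.34), Adal (−0.35), Higd2a (−0.35) and Proca1 (−0.98). The activity-induced list had a median of 0.34 (23 of 24 above 0, camera adjusted p 7.20e-10), or 0.104 with an estimated correlation. Its difference in mean log2 CPM was 0.375, which became 0.235 without targeted library 17728 and 0.511 without 18749. The list of protein stress genes had a median of 0.21 (11 of 11, 9.25e-05), or 0.349 with an estimated correlation, with 3 genes higher adjusted over the list alone and 0 over all genes. Over both sexes of D1D2 mice edgeR called 0 genes, DESeq2 7 and limma-voom 0, with 655 at an unadjusted p under 0.05. Fosb was at 0.34 there (p = 0.0488), and Lars2 (7.19), Mir6236 (6.56), n-R5s194 (6.48), Gkn3 (−1.12), Serpinb1a (−0.57) and Zfp964 (−0.41) did not pass. Small RNA genes, n-R5s194 and Mir6236 among them, held 33.4% of the counts in female targeted 19610 and 32.5% in male targeted 18919. Both libraries enter these values. The interferon list had a median of 0.32 (25 of 25, camera adjusted p 3.37e-33), or 0.105 with an estimated correlation.

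Averaged over the 6 arms, the imprinted zinc finger gene Plagl1 (0.27), the phospholipase gene Plcd1 (0.26) and the xylulose kinase gene Xylb (0.27) had the smallest p among higher genes and did not pass. Bod1 (−0.17), Cop1 (−0.18) and Paip2b (−0.14) led the lower ones without passing. Fosb was at 0.15 (SE 0.10, p = 0.136). EdgeR, DESeq2 and limma-voom each called 0 genes, with 2419 at an unadjusted edgeR p under 0.05. At the level of mean log2 CPM, the antigen presentation list differed by 0.81 over the 6 arms with 6 arms higher (permutation p 0.0011, adjusted 0.0044 over 4 lists). The interferon list differed by 0.63 with 5 arms higher (0.0124, adjusted 0.0165), the lymphocyte list by 0.84 with 6 arms higher (0.0075, adjusted 0.015) and the activity-induced list by 0.09 with 3 arms higher (0.200). These 4 tests were chosen after the arms had been compared. Female D1D2 mice held the largest differences of the 6 arms, at 1.84 for antigen presentation, 1.67 for interferon and 1.61 for lymphocytes. Control libraries far below others of their groups enter these differences: 19754, 19599, 19750 and 19598 in female D1D2, 18386 in male D2 (2.964 for antigen presentation), 18383 in male D1 and 19511 in male D1D2 mice. No test without them was made, since they stand out in the measured lists themselves.

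Activity-induced genes differed between the D1 and D2 arms in their response to the Fosb guide. Arc, which organises synaptic endocytosis, the phosphatase gene Dusp1, the transcription factor genes Egr1, Egr4, Nr4a1 and Nr4a3 and the clock gene Per1 moved up in D1 mice relative to D2 mice when adjusted over the list alone. Fosb itself went the same way without passing over all genes. Ion channel genes leaned up and ribosomal protein genes down. The activity-induced list had a median difference of 0.47 (23 of 24 above 0, camera adjusted p 1.0e-12), held with an estimated correlation (0.0326) and by fry (0.0175). The difference in its mean log2 CPM was 0.502 (SE 0.146), and 0.42 (SE 0.147) without male D1 control 17789. Its 7 genes adjusted over the list alone, named after their values were seen, were Arc (0.93), Nr4a3 (0.86), Egr4 (0.82), Nr4a1 (0.81), Egr1 (0.74), Dusp1 (0.52) and Per1 (0.48), against 0 over all genes. Fosb differed by 0.78 (SE 0.25, p = 0.00247), and over 16 alternative settings by 0.53 to 0.92. In females alone the Fosb difference was 0.78 (SE 0.33, p = 0.0198) and in males 0.78 (SE 0.37, p = 0.0409). In batch 1 alone the male difference was 0.289 (SE 0.475) and that over both sexes 0.526 (SE 0.290), neither above 2 standard errors, and over all alternatives the male value ran from 0.289 to 1.076. The list's median difference was 0.45 in females, at 0.414 with an estimated correlation, and 0.53 in males, at 0.0345 with an estimated correlation. The ion channel list had a median difference of 0.31 (26 of 26, camera adjusted p 2.22e-06), or 0.446 with an estimated correlation, and the ribosomal protein list one of −0.21 (0 of 18, 1.0e-12), or 0.421 with an estimated correlation. One gene passed over all genes, Rnu2-10 (−6.76, SE 1.20, adjusted p 0.00771). Its level was high in single libraries of several groups, with 126 CPM in male D1 control 17789, 106.1 in female D1 control 16597, 84.75 in male D1 control 18068 and 58.52 in female D2 targeted 18167. Without 18167 it stayed negative and 0 genes passed. Crebzf (0.40), Irs4 (−2.19), Fam19a4 (−0.997) and Tmem35a (−0.37) did not pass, and 929 genes had an unadjusted p under 0.05. In females 1 gene passed, Gm9887 (−5.49, SE 1.03, adjusted p 0.0224; −0.06 without library 16583, not passed), with 911 at an unadjusted p under 0.05. Fezf2 (3.34), Inhba (1.13), Rnu2-10 (−7.09), Apoo-ps (−2.22) and Entpd4b (−1.29) did not pass in females. In males edgeR, DESeq2 and limma-voom called 0 genes, with 468 at an unadjusted p under 0.05, and Hic1 (1.19), Wdr90 (0.72), Snapc4 (0.67), Setd4 (−1.72), Rnu2-10 (−6.42) and Dnah7a (−1.16) did not pass.

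**Figure D2:**
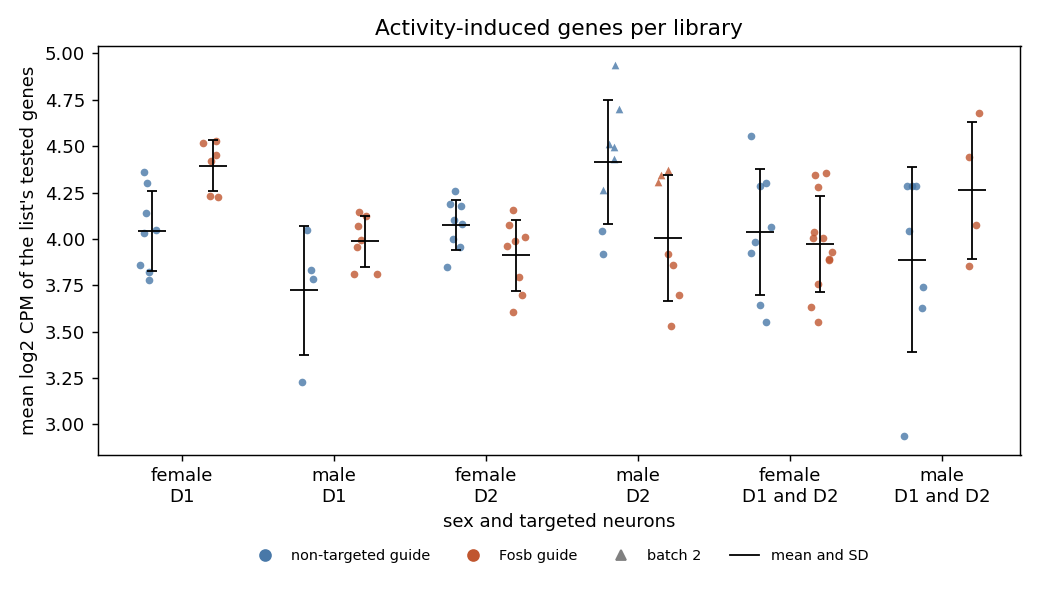
Mean log2 CPM of the activity-induced list for each library, by sex, cell type and guide, with the mean and SD of each group and batch 2 libraries as triangles. The Fosb guide means lie above the controls in female D1 mice (4.40 against 4.04) and below them in male D2 mice (4.004 against 4.41), where the batches are unbalanced between the guides. Within batches the male D2 difference was −0.221 (exact permutation p 0.0349), with 3.752 against 3.98 in batch 1 and 4.34 against 4.557 in batch 2.

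The response to the Fosb guide was also compared between females and males. For D1 delivery 1700057H15Rik, a predicted gene, was the single gene whose response differed, and the glycosylation gene Mgat2 and the Notch ligand gene Dll1 had small p without passing. For D2 delivery neuropeptide precursor genes leaned higher in females. For delivery to both cell types the AP-1 gene Fosl2 and the lysosomal trafficking gene Lyst were lower in females without passing. 1700057H15Rik differed by 7.50 (SE 1.3, adjusted p 0.00210), with 949 genes at an unadjusted p under 0.05. Its values come from targeted library 17376 (3.96 CPM) and male control library 18383 (6.75 CPM), and without either library it did not pass (4.13 and 3.71). Limma-voom called 0 genes. Dll1 (−0.86), Mgat2 (−2.29), Xab2 (−0.44), Kdm5d (4.91), Ddx3y (4.73) and Uty (4.48) did not pass. Mgat2 had an SD of 164 CPM in female D1 controls, above their mean of 118. For D2 delivery edgeR, DESeq2 and limma-voom called 0 genes, with 321 at an unadjusted p under 0.05. Htr7 (1.01), Pamr1 (−0.97), Pole2 (−4.27), Setd4 (−1.49), Lars2 (7.84) and Mir6236 (7.30) did not pass. The female D2 targeted libraries dominated by few genes, 17907 and 18432, enter the values of Lars2 and Mir6236. The neuropeptide list had a median difference of 0.15 (10 of 13 above 0), at 0.0246 with an estimated correlation and 0.953 by fry, and no member passed. For delivery to both cell types edgeR and limma-voom called 0 genes and DESeq2 1, with 1069 at an unadjusted p under 0.05. Fosl2 (−1.10), Lyst (−0.65), Ubxn10 (1.497), Mettl7a1 (0.55) and Higd2a (0.44) did not pass. Fosb responses differed by −0.07 for D1 (p = 0.841), −0.07 for D2 (p = 0.831) and −0.52 for delivery to both (p = 0.131).

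The fold changes of the 6 arms were correlated across genes in 15 pairs. Genes are not independent replicates, so each r was compared with 100 shuffles of the guides. Female and male D1 mice had r = 0.08, female D1 and female D2 mice r = −0.12. Male D2 and female D1D2 mice had the highest of the 15, r = 0.51 (rho 0.32), where the central shuffled values ran from −0.549 to 0.501. Its permutation p of 0.0693 was the lowest of the 15, shared with female D2 and female D1D2 mice (r = 0.29), and was 0.52 after adjustment.

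Female and male controls differed most widely. The X-inactivation transcript Xist and its antisense partner Tsix were higher in females, and the Y-linked Kdm5d, Uty, Ddx3y and Eif2s3y were lower. Beyond these, ribosomal protein genes such as Rps24 and Rpl5 were lower in females. Genes of neuronal excitability and synapses such as Kcnd2, Shank3 and Drd2, the dopamine D2 receptor gene, were higher. Single glial, vascular and immune genes, among them Gpr17, Csf1r, Pdgfrb and Cd4, were higher as well, while others such as Aspa and Klra8 were lower. In all 7259 genes passed with edgeR, 3900 higher and 3359 lower in females, with 10113 at an unadjusted p under 0.05. Which direction holds more genes depends on the scaling, since 2792 of 7856 were higher with DESeq2 size factors and 2966 of 8290 with the DESeq2 test. Limma-voom called 6036, 3360 of them higher, and 3 surrogate variables left 3409, of which 3161 were shared. With no batch term 5681 were called, 2644 of them higher, and only 2808 were shared. Because batch 2 held male D2 libraries alone, means are given for batch 1, with 24 female and 13 male controls. Xist was at 55.9 ± 16.5 against 0.309 ± 0.180 CPM (7.65), and Ddx3y at 0.838 ± 1.94 against 79.3 ± 13.9 CPM (−7.63). Tsix (6.82), Kdm5d (−7.77), Uty (−7.83) and Eif2s3y (−7.46) followed, and the sex-linked list held its call with an estimated correlation (0.0184). Whether reads were counted by strand is not given in the sources used here, so reads of Tsix and Xist, which overlap on opposite strands, were not shown to be kept apart. Autosomal and mitochondrial genes made up 3796 of the higher and 3242 of the lower genes, the X chromosome 104 and 111, and the Y chromosome 0 and 6. The higher autosomal and mitochondrial genes had a median exon length of 5030 bases and the lower ones 2414. Whether sex or other differences between the female and male libraries gave these autosomal differences was not tested.

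Among ribosomal protein genes 17 of 18 were lower in females, 18 adjusted over the list alone (median −0.43, camera adjusted p 6.06e-16), or 0.319 with an estimated correlation. Rps24 was at 443 ± 98.8 against 682 ± 220 CPM (−0.68), beside Rps27a (−0.66), Rpl5 (−0.49) and Rps6 (−0.44). The ion channel list had 13 higher genes, 13 adjusted over the list alone, with Cacna1h (0.56) and Kcnd2 (0.54), and was at 0.465 with an estimated correlation. The dendritic spine list had 11, also 11 adjusted over the list alone, with Shank3 (0.67), Ppp1r9b (0.66) and Tiam1 (0.44), and the dopamine signalling list 8, or 9 adjusted over the list alone, with Drd2 (0.70) and Adcy5 (0.65). Both were at 0.465 with an estimated correlation. The medium spiny neuron list had 6, or 9 adjusted over the list alone, with Rasd2 (0.73), and was at 0.526 with an estimated correlation. Higher genes of other cell types were Gpr17 (0.74) and Cspg4 (0.65) of oligodendrocyte precursors, Slc1a3 (0.47) of astrocytes, Csf1r (0.66) and Cx3cr1 (0.47) of microglia, Pdgfrb (0.60) of vessels and Cd4 (0.69) of immune cells. Oligodendrocyte genes went both ways, with Mag higher (0.40) and Aspa lower (−0.34). Cholinergic genes Slc18a3 (0.84) and Chat (0.63) and the secreted peptide gene Vgf (0.76) were higher. Among genes of at least 1 CPM those that rose most also held Myoc (2.503), Pole2 (1.94, but −0.13 with the DESeq2 test, and 16.3 ± 58.1 against 2.07 ± 1.16 CPM in batch 1), Gdf3 (1.71), Ighg2c (1.58), mt-Atp6 (1.53) and Slc13a4 (1.14). Of these Ighg2c (0.0759), mt-Atp6 (0.0860) and Slc13a4 (0.0873) did not pass in batch 1 alone (adjusted p in brackets), and mt-Nd5, also mitochondrial, was lower (−0.52). Those that fell most held the natural killer receptor genes Klra8 (−1.69), Klra4 (−1.35) and Klri2 (−1.15) and the noncoding Bc1 (−1.10). Fosb was at 0.30 (SE 0.15, adjusted p 0.140), with 7.24 ± 1.75 against 6.04 ± 2.88 CPM in batch 1.

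Across libraries the lymphocyte list, which holds T cell genes such as Cd3e, tracked the interferon list. Within batch 1 Pearson r was 0.893 and Spearman rho 0.661 over 78 libraries, permutation p 1e-05 for r, the smallest the resampling can give, and 7e-05 adjusted over 14 relations. Without the 2 libraries farthest from the median r was 0.855. In batch 2 r was 0.821 (n = 9, exact permutation p 8.90e-04), or 0.959 without the 2 farthest. The reactive astrocyte list, with Gfap, tracked the lymphocyte list with r = 0.904 in batch 1. The lymphocyte list and Fosb had r = 0.055, and the cortical list and Fosb r = −0.081, both in batch 1. The lymphocyte list and the activity-induced list had r = 0.328 there (permutation p 0.01 adjusted) and rho 0.183 (0.261 adjusted).

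**Figure D3:**
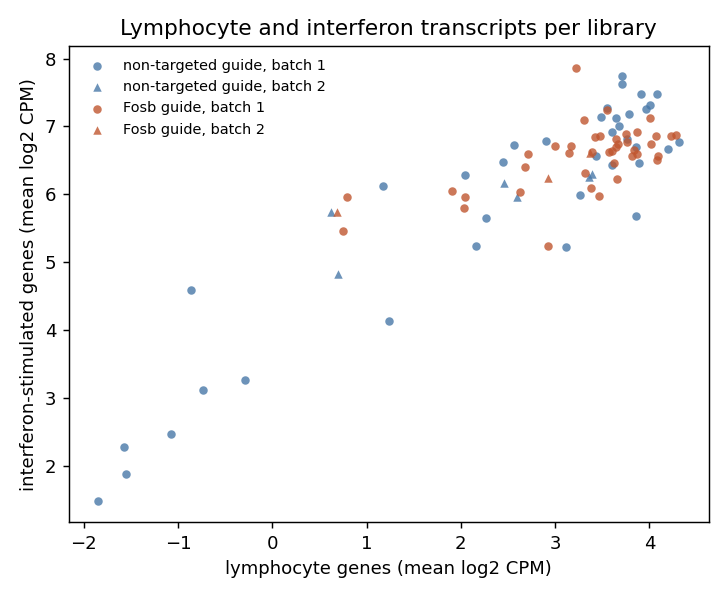
Mean log2 CPM of the interferon list against that of the lymphocyte list for each library, by guide and batch. The 7 lowest lymphocyte levels, from −1.85 to −0.29, all belong to libraries with the control guide.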

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

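Tests chosen only after the result was seen are those of 1 animal in 2 groups, of batch by sex and on the activity-induced list, of genomic DNA and of a shared change for the 16 male D2 genes, the lymphocyte covariate, the libraries left out and the mean over 6 arms for the interferon genes, the exact permutation test of the antigen presentation list, and all tests by other splits of the libraries. The 4 tests of the D1 and D2 difference in Fosb and the exact permutation test of the interferon list were set before their results were seen.

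Fosb and the activity-induced genes such as Arc, Egr1 and Nr4a1 responded differently to the Fosb guide in the D1 and D2 arms, while no arm's own Fosb difference passed with all libraries. The Fosb difference was 0.778 on the log2 scale over both sexes, 0.777 in females and 0.778 in males, each past a single-gene test, and the activity-induced list differed by a median of 0.466 over both sexes and 0.533 in males. Cortical tissue in the dissection is argued against, since the Fosb difference was 0.853 (SE 0.248) with the cortical list as a covariate, as are immune infiltration, with 0.796 (SE 0.245) under the lymphocyte covariate and 0.493 (SE 0.137) for the activity-induced list, the 4 libraries dominated by few genes, with 0.84 (SE 0.244) without them, and 1 animal in 2 groups, with 0.781 (SE 0.250) without the closest pair of libraries, 18722 and 18749. Sequencing batch is argued against as the whole cause only by tests chosen after the result was seen. The female libraries, all of batch 1, gave 0.777 (SE 0.327), a value already known from the main fit. The activity-induced list differed by 0.505 (SE 0.176) in batch 1 alone. The batch test set before, on Fosb over both sexes in batch 1, gave 0.526 (SE 0.290). That is under 2 standard errors, so by itself it decided nothing. Batch stays open for Fosb in males, which was at 0.289 (SE 0.475) in batch 1 with fewer male D2 libraries, and so does the Cre line, which differs between the D1 and D2 arms and is untested.

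The 16 genes that rose in male D2 mice were highest by far in library 3632 of the Fosb guide in 14 cases, and library 3128 of that guide was above every control in 15. Several of these genes lie within or beside one another, so the counts are not of independent genes. Of these genes 3632 held 3877 CPM of Gm10800, 735.4 of Gm21738, 485 of Gm10801, 304.7 of Gm26870, 218 of Gm33838, 113.3 of Setd4, 84.1 of Gm10722, 45.97 of Gm10717, 42.84 of Gm10718, 40.11 of Gm11168, 28.06 of Gm10719, 4.704 of Gm41335, 3.495 of 4930500H12Rik and 3.333 of Gm45740. Without 3632 0 of the 16 passed, but the median log2 fold change was still 1.335 (median SE 0.552), against 3.362 with it. That median includes 3128 and comes from genes chosen by their calls with 3632. A rise of that size in every targeted library is argued against, since 2756 was above every control in 1 of the 16. The batch 1 targeted libraries reached at most 10.44 CPM of Gm10800. The highest control, at 156.8, was taken over both batches, so this comparison decides nothing about batch 1. A change shared by 3632 and 3128 cannot be told apart from separate changes in single libraries. Genomic DNA in that library cannot be told apart from other sources, since its olfactory and vomeronasal receptor counts were 0.884 times those of the highest other batch 2 library (238.2 against 269.4 CPM summed over these genes), but all batch 2 libraries had at least 80.19 and batch 1 libraries at most 72.36, so that the comparator may share it. Library 3632 also had the most genes with a count (40854, next 36436), 3128 is the comparator with the highest receptor counts, and no biological explanation was tested.

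Interferon-stimulated and antigen presentation genes were higher as lists with the Fosb guide in female D1D2 mice, with no member passing in edgeR, against controls of which 4 of 8 (19754, 19599, 19750 and 19598) had interferon levels from 1.49 to 3.26 and the others from 7.13 to 7.63. The libraries dominated by few genes are argued against, since the mean log2 level of the interferon list still differed by 1.721 (SE 0.572) without them, against 1.672 (SE 0.548) with them. A chance distribution of infiltration between the guides fits the exact permutation p of 0.0512 for the interferon list. It stays open at 0.0257 for the antigen presentation list, and both were 0.278 adjusted over 36 tests. The prediction for a difference between the guides shared by the 6 arms was met, with a permutation p of 0.0124 over all arms. That mean includes female D1D2 mice, which prompted the test, at 1.672. The other arms ran from −0.105 (female D1) to 0.847 (male D2), so this p cannot decide whether the difference is shared. Low control libraries 18386, 18383 and 19511 of other arms contribute to it as well. More lymphocytes in the targeted libraries cannot be told apart from these explanations. The female D1D2 difference was 0.466 (SE 0.279) with the lymphocyte covariate, and that list holds the same kind of signal. A first form of these tests, on the median of gene fold changes, gave 0.33 (median SE 0.49), 0.41 (0.28) with the covariate and 0.36 (0.52) without the 4 libraries, and the reading of the first 2 tests together was also set after they were seen.

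Of 76 groups tested for a sample far from the others, 33 held one. Most of these measures are genes taken because they had been called, to which a chance rate of about 1 in 20 does not apply; of the 44 groups of Fosb, total counts, Xist and Ddx3y, 8 held one. Fosb was at 13.34 CPM in female D2 targeted library 17907 and 11.88 in female D2 control library 17910. Total counts were 59328186 in female D1 targeted library 17376. Xist was at 9.901 CPM in male D1D2 targeted library 18919 and 0.4036 in male D2 control library 19099. Ddx3y was at 37.03 CPM in 17376, 4.769 in female D1 control library 17457 and 0.5084 in female D2 control library 17906. Gm9887 was at 890.3 CPM in female D1 control library 16583, where the next library had 4.18, and differed by −5.492 between the D1 and D2 arms of females. Gm23935 was at 173648 CPM in 18919, where the next had 2690. Gm13767 was at 2.131 CPM in male D2 targeted library 3128 and Gm47518 at 12.03 in 2756. 1700057H15Rik was at 6.747 CPM in male D1 control library 18383, 3.958 in 17376 and 0.2168 in 17457, and its response differed by 7.502 between the sexes. Rnu2-10 was at 106.1 CPM in female D1 control library 16597, 58.52 in female D2 targeted library 18167, 12.61 in male D1 targeted library 19507 and 7.984 in 3632, and differed by −6.755 between the D1 and D2 arms. The neuropeptide list differed by a median of 0.145 between the sexes with D2 delivery.

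Counts of genes were compared with 20 other splits of the libraries, so that each real split is 1 of 21. For the 7259 genes that differ between female and male controls 1 split, the real one, was as large and the highest other gave 2227. Chance is argued against there at the smallest share that 21 splits can give. The splits cannot separate sex from other differences between the female and male libraries. For the 1 gene of the D1 and D2 difference over both sexes, Rnu2-10, 1 split, the real one, was as large and the highest other gave 0. It stayed negative without library 18167, where it no longer passed, and a lost call alone decides nothing. Chance is not taken as excluded for it, since its high levels lay in single libraries of several groups. Chance cannot be excluded for the 16 male D2 genes, as 3 splits gave as many (highest other 19). It cannot be excluded either for the single genes of female D1 (21 as large, highest other 6), male D1D2 (14, highest other 4287), the D1 mean (15, highest other 3), the sex difference in D1 (18, highest other 4) and the D1 and D2 difference in females (20, highest other 12). For the comparisons with 0 genes all 21 splits were as large by construction, with highest other counts of 2 (male D1), 3 (female D2), 21 (female D1D2), 0 (D2 mean), 2031 (D1D2 mean), 1 (mean of 6 arms), 8 (sex difference in D2), 1466 (sex difference in D1D2) and 1128 (D1 and D2 difference in males). The splits with 4287, 2031, 1466 and 1128 genes stood beside medians of 0 or 1 gene, and what made them large was not tested.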

How the results depend on the processing

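Settings chosen after the results were seen are the library sets without 4 or 2 libraries, the fit without 18722 and 18749, whose counts are the closest of all pairs, the lymphocyte and cortical covariates, the minimum of 1 CPM for counts of genes, batch 1 for the sex controls and for the D1 and D2 difference over both sexes, the D1 and D1D2 arms alone for the sex controls, and the single libraries left out of female D1, male D2 and female D2 groups, of the sex difference in D1, or (17789) of the D1 mean and the D1 and D2 differences. No paired analysis was possible because no replicate number is shared between groups. Of the main results under the alternatives 314 kept their value or side of the threshold, 70 counts moved by over 1.5 times, 10 values reversed and 2 grew stronger. Of the named genes and lists 3982 kept theirs, 753 grew weaker, 26 stronger, 166 moved and 9 reversed. For the mean of 6 arms a fit of these arms alone is the same fit and gives no further value. Causes were not tested except where stated. Female D1 counts were 0 with arms alone, DESeq2, limma-voom and 3 surrogate variables, and 0 to 1 over libraries left out, with 0 without control library 16583, which holds the gene. Male D1 counts were 747 with limma-voom and 1 without the 2 libraries of mixed sex transcripts, and 0 in each fit without a control library. Female D2 counts were 4 with DESeq2, 1 without the 2 libraries and 3 with the lymphocyte covariate. Male D2 counts were 0 with arms alone, limma-voom, batch 1 alone (fewer samples) and without library 3632, 5 with DESeq2, 6 at 1 CPM or more (fewer genes tested), 122 with no filter and 427 with no batch term. Female D1D2 counts were 2 with DESeq2, 194 with limma-voom, 120 with 3 surrogate variables and 5 without the 2 libraries. Male D1D2 counts were 0 with arms alone, limma-voom, 3 surrogate variables and without the 4 libraries dominated by few genes, 2 without the 2 libraries, and 0 to 4 over libraries left out. D1 mean counts were 26 with limma-voom and 0 with arms alone, no filter, 3 surrogate variables, the cortical covariate and without either library set or control library 16583. D1D2 mean counts were 7 with DESeq2 and 3 with the lymphocyte covariate. For the sex difference in D1 counts were 0 with arms alone, limma-voom, 3 surrogate variables, the lymphocyte covariate, 1 CPM or more and without the 2 libraries, library 17376 or library 18383, and in D1D2 they were 1 with DESeq2 size factors, the DESeq2 test and 1 CPM or more. For the D1 and D2 difference counts were 2 with DESeq2 and 0 with limma-voom, 3 surrogate variables, batch 1 alone and without library 18167 over both sexes, 0 with arms alone, no filter, limma-voom, 3 surrogate variables, the cortical covariate and without the 2 libraries or library 16583 in females, and 1 with 3 surrogate variables in males. The sex controls gave 3409 genes with 3 surrogate variables. Without 18722 and 18749 counts were 0 for the D1 mean, 1 for the D1D2 mean and 1 for the sex difference in D1D2, and Fosb in male D1D2 mice was at 0.89 (adjusted p 0.0232). List calls fell from 196 to 6 with an estimated correlation and 18 with fry. Fosb in female D2 mice was at −0.47 without library 17907. Fosb in male D2 mice reversed to 0.17 in batch 1 alone. In male D1D2 mice it reached 0.89 without library 18749, and left-out fits ran from 0.35 to 0.89; they ran from 0.33 to 0.50 in female D1 and 0.43 to 0.53 in male D1 mice, and the male D2 value was −0.17 without 3632. In batch 1 alone Gm10717 reversed to −1.51, Gm47518 to −0.44, Setd4 to −0.19 and Gm13767 to −0.19 in male D2 mice. Gm23935 reversed to −0.57 without library 18919 and without the 4 libraries, which include it, and its left-out fits ran from −0.57 to 4.73. In the sex controls Gabrb1 reversed to −0.065 with no batch term and Pole2 to −0.13 with DESeq2. The ribosomal protein list in female D1 mice reversed with 3 surrogate variables (adjusted p 5.93e-04). Among correlations of fold changes a minimum of 1 CPM reversed female D1 with male D2 (0.006), female D1D2 (0.048) and male D1D2 (0.04), and 3 surrogate variables reversed female D1 with female D1D2 (0.142), male D1 with female D2 (−0.071) and male D1D2 (−0.008), female D2 with female D1D2 (−0.07) and male D1D2 (−0.058), and female with male D1D2 (−0.118). Depth left for other genes is low in the 4 libraries in which 10 genes hold over 90% of the counts, and 10 genes held 79.1% in 17457 and 62.6% in 16754. On simulated data with the real library sizes 25% to 56% of genes changed 1.5-fold, all with a mean of at least 1 CPM, were recovered.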

Other observations

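The values here were chosen after the data were seen, and no test was attached to them. Both Xist and the Y-linked Ddx3y were abundant in 2 libraries labelled female, female D1 targeted 17376 (Xist 35.2 and Ddx3y 37.0 CPM) and female D1D2 targeted 19749 (29.96 and 30.9 CPM). The medians were 59.0 and 0.132 CPM over 50 female libraries and 0.215 and 71.5 CPM over 37 male libraries. Library 17376 was at 59.6% of the female Xist median and 51.8% of the male Ddx3y median, and 19749 at 50.8% and 43.3%. They had the largest and second largest total counts of batch 1, and both were kept in the means of their groups. Lower Ddx3y levels were found in female D1D2 control libraries 19598 (7.20 CPM) and 19762 (5.31), female D1D2 targeted 19610 (4.82) and female D2 targeted 17907 (7.18) and 18432 (5.49). Xist was at 3.89 CPM in male D1 targeted 18130 and 3.44 in 18368.

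The lowest mean log2 CPM of the lymphocyte list were −1.85 and −1.57 in female D1D2 control libraries 19754 and 19599, −1.55 in male D2 control 18386, −1.07 in female D1D2 control 19750, −0.86 in male D1 control 18383, −0.73 in male D1D2 control 19511 and −0.29 in female D1D2 control 19598. The interferon list was at 1.49 in 19754. The lymphocyte and interferon lists shared 0 genes. The first and second principal components of the log2 CPM values held 30.7% and 23.7% of the variance. The first had an absolute correlation of 0.816 with the ribosomal protein list level and 0.788 with batch 2. Among 3741 pairs of libraries the lowest chi-square per degree of freedom was 3.63, between male D1 targeted 18722 and male D1D2 targeted 18749, then 6.36, between 17907 and 19610, against a median of 211. Among the 296 pairs within groups the lowest was 13.4, between female D2 targeted 17907 and 18432, against a median of 178.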
